A study of Homo sapiens with 12 samples.

How the data were processed

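The series measured acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, by chromatin immunoprecipitation and sequencing in 12 samples of human cancer cell lines. Per the labels' protocols, chromatin was precipitated with 1 antibody throughout and libraries were made with a commercial kit for this assay. Per the submitters' processing notes, reads were aligned with BWA to the hg19 build; the version, the control and any pooling of replicates are not given in the sources used here. Peak names in the 2 Ishikawa lists begin with MACS, the name of a peak caller; the caller of the other lists is not given in the sources used here. Each sample has its own deposited peak list, so lists were treated as called per sample.

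The deposited lists came in 3 forms. The H358 and H2009 lists, 8 in all, had 10 columns in the narrowPeak form; the HCC95 and BICR31 lists had 9 columns in the broadPeak form; the 2 Ishikawa lists had 5 columns. In the narrowPeak and broadPeak lists the deposited values per peak were a fold enrichment ratio over local background, a −log10 p, a −log10 q and a score equal to the whole part of 10 times the −log10 q. The narrowPeak lists also held a deposited summit offset in bases, an other kind of value that was not used here. The Ishikawa lists held 1 deposited score per peak, starting at 50. The lowest deposited −log10 q was 1.31 in the narrowPeak lists and 1.00 in the broadPeak lists. All of these are the authors' values for a peak within its own list. They served here to rank or filter peaks of that list, to score its clusters and to describe its peaks. The value in the cluster score was the fold enrichment, or the deposited score in the Ishikawa lists. File form moved with the type of line as grouped here: the lung adenocarcinoma lists were narrowPeak, the squamous lists broadPeak and the endometrial lists 5-column. Lists of 1 form alone are given beside the pooled agreement of replicates; no form held lines of different types in this grouping, although HCC95 and BICR31, both broadPeak, come from different organs. Read numbers are not part of a peak list, so sequencing depth is unknown and the number of peaks and called bases stand as the measure of how much each list could show.

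Groups followed the labels: H358 (2 libraries), H2009 (2), HCC95 (1), Ishikawa (2), BICR31 (1), and 4 further H2009 libraries labelled Empty, Control, e3KRAB1 and e3KRAB2 (1 each). The labels do not say whether replicates were separate cultures, so p-values across libraries measure only the spread between these libraries, which may be technical. The BICR31 sample carries a lung adenocarcinoma label, while the design text of the series names BICR-31 as head and neck squamous; the design text was followed. The labels do not expand e3 or KRAB. They state No treatment for every sample, so untreated here only names the 8 libraries without an Empty, Control or e3KRAB label.

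Peaks on chromosomes 1 to 22 and X were used, which left out 556 of the deposited peaks, or 0.238%. Overlapping peaks (minimum overlap 1 bp) of the 8 untreated lists were merged into regions. A region counted as specific to a line when every library of that line and no library of the other lines had a peak in it, and as exclusive to a pair of lines by the same rule for both. Agreement of libraries was the base-pair Jaccard index, the called bases in both lists divided by those in either, with an exact one-sided permutation test over the 420 ways to place 3 pairs among 8 libraries. The exclusive share of a pair was its exclusive regions as a percent of these plus the regions specific to either of its lines. Regions found in only 1 of the 2 libraries of a line were thus left out of it. This share is not part of the design and was added after the counts had been seen. So were Fisher tests of line-specific regions in 2 Mb windows (7295 windows over the 5 lines, Benjamini-Hochberg adjusted). For the study loci, called bases in fixed windows were ranked among 10000 random windows of the same length that held at least part of 1 merged region. Broad clusters were peaks joined within 12.5 kb, scored by the sum of peak width times the authors' value, and kept above the point where the ranked, scaled curve reached slope 1; this is a stand-in for the usual procedure, which needs read signal. Regions of Empty and Control without a peak in either e3KRAB list were compared with the mirror set by a two-sided Fisher's exact test over regions, which compares these libraries and not conditions. Shares carry 95% Wilson intervals, which cover counting error only. Neighbouring peaks and regions are not independent replicates.

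The build of the gene table at hand, GRCh38.p14, was not that of the files, so none of its positions were used. By the rule fixed before the data were examined, the planned tests of gene lists near line-specific regions and at promoters, and the planned removal of peaks near transcription starts from the clusters, were not run; the 5 widest line-specific regions per line and the regions in the study windows were named by position, of which the text gives a part. The loci MYC, KLF5, USP12 and PARD6B were placed from general knowledge of hg19, rounded to 10 kb, and the major histocompatibility complex likewise, rounded to 100 kb. As a check of that placement, a peak was sought within 10 kb of each start: all 8 untreated libraries had one at MYC, USP12 and PARD6B, and 4 of 8 at KLF5. Windows were the gene plus or minus 500 kb, and 350 to 550 kb and 700 to 900 kb on the 3′ side of MYC.

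Alternatives fixed beforehand were a stricter threshold (the highest-ranked 50% of each list), lists of equal length, each replicate left out, 1 kb bins, a region counted as present only when 50% covered, other overlap measures, other windows, other stitching distances and scores, and other reference sets for the e3KRAB comparison. Functions were tested on simulated lists of 24405 merged regions with known membership, where 15 of 15 line-specific and pair counts and the 1 planted dense window were recovered with 0 false windows. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with seed 7 for random windows.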

Results

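H3K27ac peaks were compared in 5 untreated human cancer cell lines. H358 and H2009 are lung adenocarcinoma lines, HCC95 is a squamous cell lung carcinoma line, BICR31 a head and neck squamous line by the design text, and Ishikawa an endometrial carcinoma line. H358, H2009 and Ishikawa had 2 libraries each, HCC95 and BICR31 had 1. On the chromosomes used, H358 held 26866 and 26954 peaks, H2009 26887 and 26412, HCC95 23400, Ishikawa 24384 and 27311, and BICR31 42148. Called bases ranged from 10.9 Mb in H2009 replicate 1 to 41.4 Mb in Ishikawa replicate 1, because median peak widths ran from 347 bp to 1507 bp. The 4 further H2009 libraries had far shorter lists, from 1375 to 3250 peaks.

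Libraries of the same line shared more called bases than libraries of different lines. The Jaccard index between replicates was 0.631 in Ishikawa, 0.444 in H358 and 0.405 in H2009. Between lines it averaged 0.236 and ran from 0.158 for H2009 with Ishikawa to 0.357 for H358 with H2009. The mean difference of 0.257 was the highest of the 420 assignments (exact one-sided permutation p = 0.00238). Within the 4 narrowPeak lists, the replicates of H358 and H2009 averaged 0.424 and the 4 cross-line pairs 0.351; with 3 assignments the smallest p is 0.333, which was the p observed (exact permutation). The broadPeak lists had no replicates and the 5-column lists held 1 line only.

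**Figure D1:**
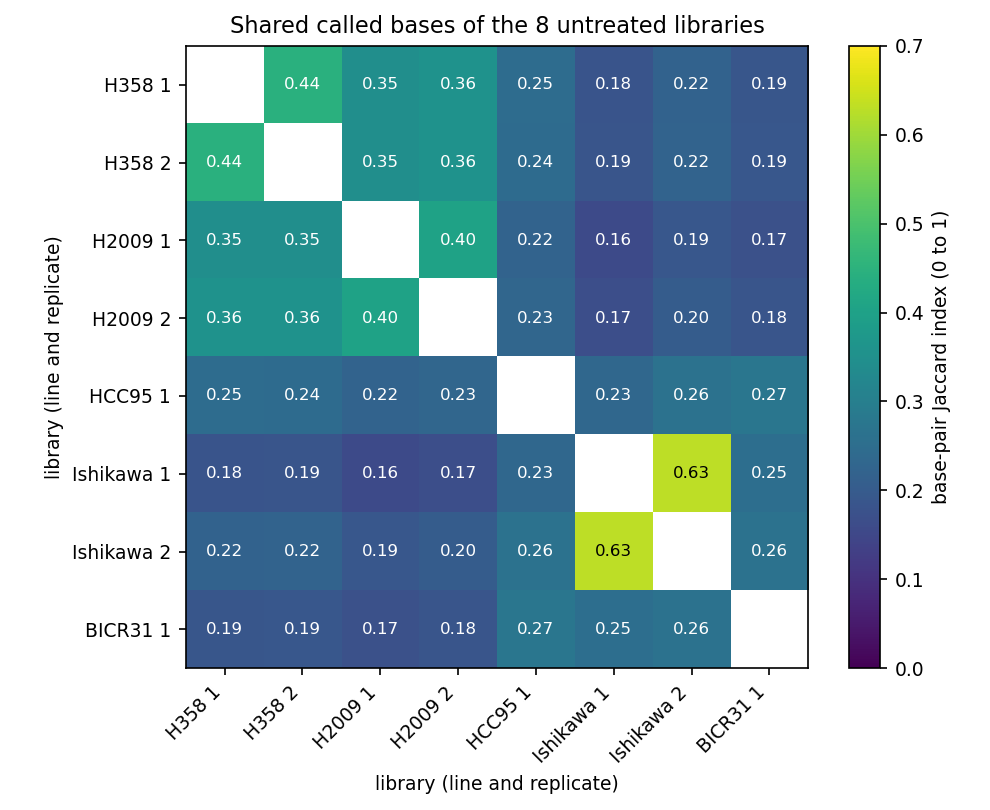
Base-pair Jaccard index (0 to 1, colour and printed value) for each pair of the 8 untreated libraries, with lines and replicates on both axes. The Ishikawa replicates stand highest at 0.631, and the H358 and H2009 libraries form a block with values from 0.346 to 0.444.

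Acetylated regions split into a common core and a large part found in 1 line. Merging the 8 lists gave 70648 regions, of which 8576 (12.1%) had a peak in every library and 39169 (55.4%) in 1 line only. Most of the latter were not replicated, since 33734 regions (47.7% of all) had a peak in just 1 of the 8 libraries. These include all regions found only in HCC95 or only in BICR31, which had 1 library each. Peaks of the core were also wider within a library, for example a median of 476 bp against 272 bp for peaks of that line alone in H358 replicate 1, although wider peaks overlap others more readily. In each library the peaks of the core carried higher values than peaks of that line alone, for example a median fold enrichment of 6.08 against 4.71 in H358 replicate 1, 4.59 against 3.57 in BICR31 and a median score of 293 against 76.0 in Ishikawa replicate 1.

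BICR31 held the most regions of its own and the lung adenocarcinoma lines the fewest. BICR31 had 15493 line-specific regions, or 37.0% of its regions (95% Wilson interval 36.6 to 37.5). HCC95 had 4382 (18.8%, 18.3 to 19.3), Ishikawa 3607 (18.1%, 17.6 to 18.7), H358 930 (5.78%, 5.43 to 6.16) and H2009 898 (5.68%, 5.33 to 6.05). With lists of equal length the BICR31 count was 5197 and the HCC95 count 6001, so the order of these lines depended on list length. A line with 2 libraries must show a region in both: when either replicate stood alone, H358 had 3935 to 3936, H2009 3619 to 4033 and Ishikawa 6147 to 6911. HCC95 then had 4635 to 4766, below Ishikawa. Fewer lists of other lines could also break exclusivity in these settings. Without BICR31 the counts were 1418 in H358, 1537 in H2009, 7067 in HCC95 and 4474 in Ishikawa.

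The widest line-specific regions lay in Ishikawa, at chromosome 18, 30346413 to 30354565 (8153 bp, scores 58.9 and 232 in the replicates) and at chromosome 11, 30441080 to 30449161 (8082 bp). In HCC95 they lay at chromosome 11, 35237599 to 35241996 (4398 bp, fold enrichment 2.06) and at chromosome 3, 189116297 to 189120399 (4103 bp, 2.24). BICR31 had its widest at chromosome 1, 246302295 to 246306246 (3952 bp, 2.72) and at chromosome 19, 12901247 to 12905065 (3819 bp, 2.01). Those of H358 were at chromosome 16, 65156122 to 65157612 (1491 bp) and 52579637 to 52580782 (1146 bp). Those of H2009 were at chromosome 4, 860770 to 862150 (1381 bp) and at chromosome 13, 114517870 to 114519205 (1336 bp). Line-specific regions had median widths of 1498 bp in Ishikawa, 629 bp in BICR31, 571 bp in HCC95, 460 bp in H2009 and 445 bp in H358.

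Regions exclusive to a pair of lines were counted to ask whether lines of the same type, grouped here as lung adenocarcinoma (H358, H2009), squamous (HCC95 from lung, BICR31 from head and neck) and endometrial, share regions that the other lines lack. HCC95 and BICR31 had 2516 such regions, the highest count of the 10 pairs. H358 and H2009 had 351, rank 5 of 10, behind Ishikawa with BICR31 (759), H2009 with BICR31 (581) and H358 with BICR31 (392). The lowest count was that of H2009 with HCC95, at 57. By count, then, 1 of the same-type pairs led and the other lay in the middle of the order. With 10 pairs the smallest share that 1 pair can be is 0.1, so the ranks describe these libraries and have no test.

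Counts favour long lists, so a further measure was added after the counts had been seen. It gives exclusive regions as a percent of these plus the regions specific to either line of the pair. A region found in only 1 of the 2 libraries of a line does not enter it. By this measure H358 with H2009 came highest at 16.1% and HCC95 with BICR31 next at 11.2%, and the highest pair of different types was HCC95 with Ishikawa at 3.83%. H358 with HCC95 had 1.32% and H2009 with HCC95 1.07%, the lowest values. The order depended on the setting: when a region had to be 50% covered by peaks, Ishikawa with BICR31 led at 12.4%, ahead of H358 with H2009 at 9.14% and HCC95 with BICR31 at 8.53%. In the higher-ranked 50% of the HCC95 and BICR31 lists alone, their share was 6.55% against 6.17% for H2009 with BICR31. The number of libraries per line mattered too. Without replicate 1, H358 and H2009 had 929 exclusive regions beside 3935 and 3619 specific ones. HCC95 and BICR31 had 3168 beside 4766 and 17378, so their share was then the higher. Without replicate 2 the order was the same, with 912 beside 3936 and 4033 against 3026 beside 4635 and 17232. If BICR31 is taken as lung adenocarcinoma, as its sample label has it, its same-type pairs are those with H2009 at 3.42% and H358 at 2.33%, ranks 5 and 7. Each same-type pair, as grouped here, also had a file form of its own, so type and peak calling cannot be told apart.

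**Figure D2:**
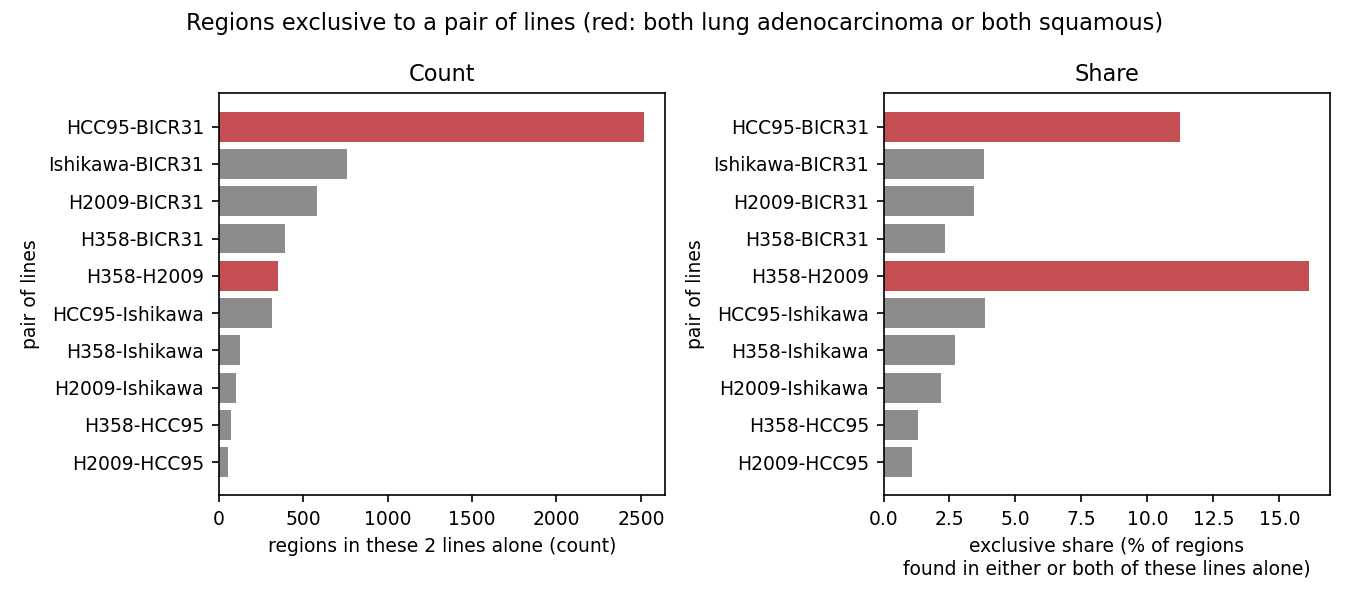
Regions exclusive to each of the 10 pairs of lines, with the lung adenocarcinoma pair and the squamous pair in red. They are given as a count (left) and as a percent of these plus the regions specific to either line (right). Specific regions had a peak in every library of the line. HCC95 with BICR31 leads by count with 2516 regions, and H358 with H2009 by share with 16.1%.

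The study is known for enhancers at copy number gains near MYC, KLF5, USP12 and PARD6B, so peaks were counted around these genes in each line. Between 350 and 550 kb on the 3′ side of MYC, a transcription factor gene that drives cell growth, both lung adenocarcinoma lines and BICR31 had more peaks than HCC95 and Ishikawa. H2009 had 9 peaks in each library and 2676 ± 49.5 called bases (SD, n = 2), H358 had 7 and 9 peaks and 3295 ± 457 (SD, n = 2), and BICR31 9 peaks and 10313 called bases. HCC95 had 2 peaks and 2712 called bases, and Ishikawa 1 and 2 peaks and 2168 ± 641 (SD, n = 2). Against random windows these were percentiles 91.3 and 93.1 in H2009, 92.5 and 95.8 in H358, 94.9 in BICR31, 78.2 in HCC95, and 54.8 and 59.1 in Ishikawa. This order depended on the threshold: in the higher-ranked 50% of each list, H358 stood at 92.4 and 96.3, H2009 at 55.4 and 79.5, BICR31 at 79.6, Ishikawa at 64.8 and 65.35 and HCC95 at 24.8, so that H2009 replicate 1 lay below both Ishikawa libraries. The equal H2009 peak counts hide different places. Both its libraries had peaks only in the regions starting at 129139053, 129165435, 129179990 and 129188080. Narrow lists can also split 1 region, as H2009 replicate 2 did at 129139073 to 129139334 and 129139580 to 129139891. Peak counts are therefore not alike across file forms, and called bases of H2009 and HCC95 were close.

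In the wider window around MYC, BICR31 had 40 peaks (percentile 99.4) and HCC95 21 (98.4), while H358, H2009 and Ishikawa lay between 83.5 and 93.7. Of its 65 regions, 10 were specific to BICR31 and 8 were exclusive to HCC95 and BICR31. Genome-wide these were 15493 and 2516 of 70648 regions, so BICR31-specific regions were no more frequent in this window than elsewhere. In the higher-ranked 50% of peaks HCC95 stood at 86.5 and H2009 replicate 1 at 50.1, and with 250 kb flanks H358 replicate 2 rose to 96.6 and Ishikawa replicate 1 to 96.5.

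Individual regions between 350 and 550 kb from MYC split by line. The region at chromosome 8, 129188080 to 129190370, had a peak in all 8 libraries. Those at 129139053 to 129140642 and at 129179990 to 129181426 had peaks in both libraries of H358 and H2009 and in BICR31, and none in HCC95 or Ishikawa. The region at 129165435 to 129165971 had peaks in the 4 lung adenocarcinoma libraries alone. Between 700 and 900 kb the picture differed: a 4506 bp region at 129547074 to 129551579 had peaks in both Ishikawa libraries (4506 and 3296 called bases) and in no other line. In that window Ishikawa stood at percentiles 74.8 and 79.3 and H2009 at 62.8 and 67.8, so neither reached 95, and in the higher-ranked 50% of peaks Ishikawa stood at 25.1 and 64.4, H2009 at 63.8 and 66.1.

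**Figure D3:**
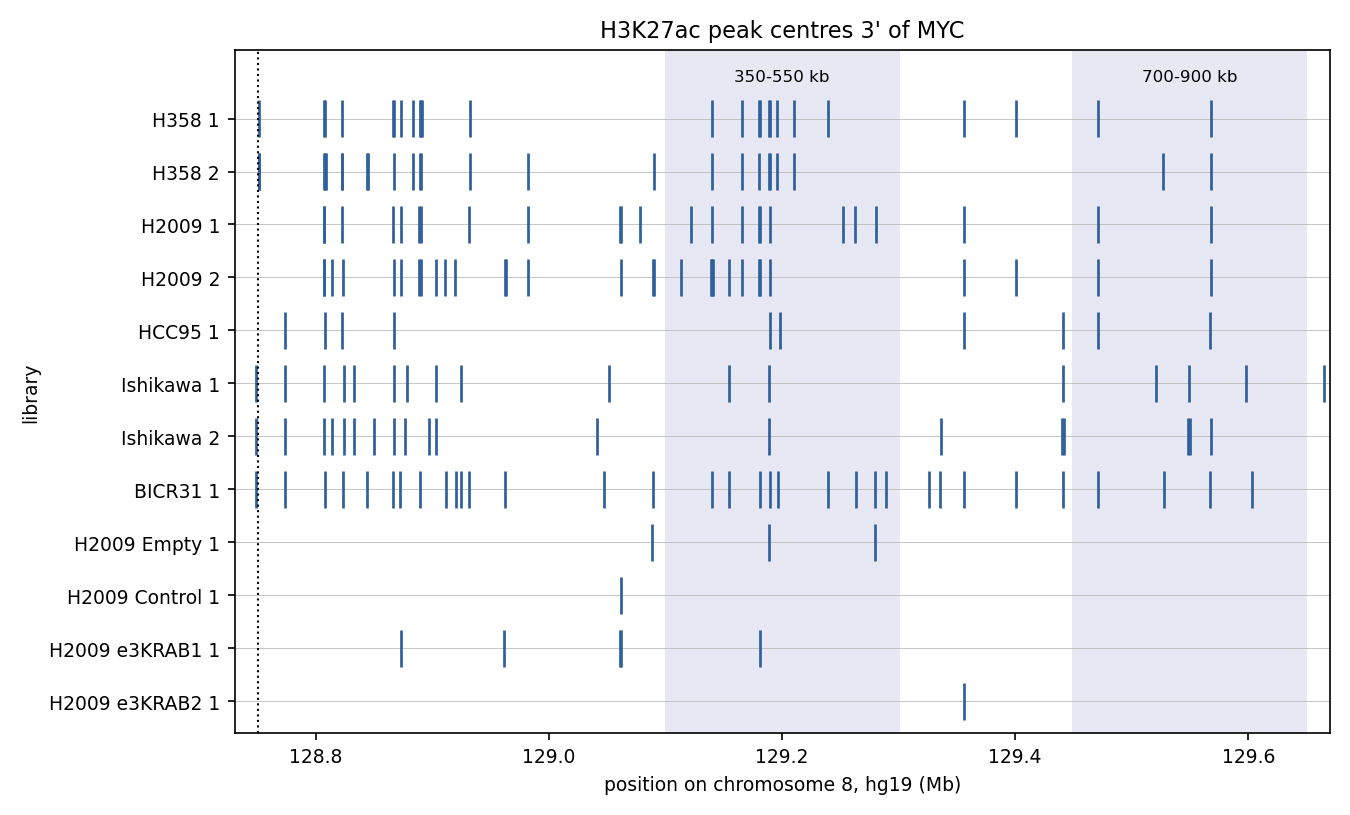
Centres of H3K27ac peaks (ticks of fixed width) on chromosome 8 of hg19, in Mb, from the start of MYC (dotted line, rounded) to 900 kb on its 3′ side, with 1 line per library. In the shaded window from 350 to 550 kb, H2009 replicates 1 and 2 have 9 peaks each and Ishikawa 2 and 1. The 9 peaks lie partly at different places in the 2 H2009 replicates, and narrow lists can split 1 region into several peaks. The shaded window from 700 to 900 kb holds a region found in Ishikawa alone.

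Around KLF5, a transcription factor gene of epithelial cells, BICR31 stood apart. Its 38 peaks and 45321 called bases in the 500 kb flanks compare with 12 peaks and 12774 bases in HCC95, 10.5 peaks and 16122 ± 4241 bases in Ishikawa, 9.5 peaks and 3461 ± 308 bases in H358 and 3.5 peaks and 1001 ± 498 bases in H2009 (means and SD, n = 2 for the last 3). Of the 46 regions there, 23 were specific to BICR31 and 3 were exclusive to BICR31 with HCC95, among them chromosome 13, 73742354 to 73744331. Genome-wide, 15493 of 70648 regions were specific to BICR31 and 2516 exclusive to that pair. The widest region with peaks in both squamous lines lay at 74002013 to 74005372, which also had a peak in 1 of the H358 libraries. BICR31 was at percentile 97.2 of random windows, HCC95 at 80.6 and H2009 at 19.9 and 31.5; the BICR31 percentile was 93.8 with lists of equal length, 94.8 in the higher-ranked 50% of its peaks and 89.5 with 250 kb flanks, each below 95. At the start of KLF5, a region at 73632287 to 73636916 had peaks in both Ishikawa libraries, BICR31 and 1 H358 library.

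**Figure D4:**
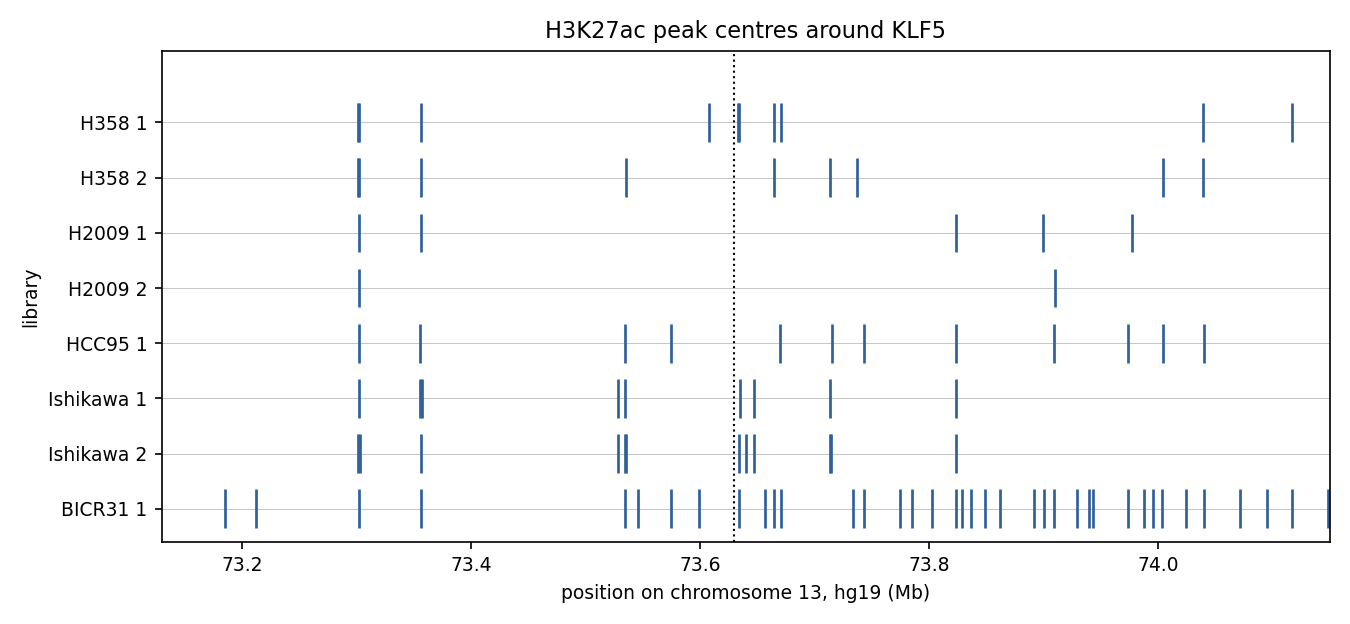
Centres of H3K27ac peaks (ticks of fixed width) within 500 kb of KLF5 on chromosome 13 of hg19, in Mb, with 1 line per untreated library and the rounded gene start as a dotted line. BICR31 has 38 peaks, most of them to the right of the gene, against 12 in HCC95 and 2 and 5 in H2009.

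PARD6B, a cell polarity gene, lay in a window where BICR31 had the most peaks and called bases. BICR31 had 50 peaks (percentile 99.2), HCC95 28 (97.0), H358 28 and 30 (94.7 and 93.0), Ishikawa 19 and 24 (92.9 and 91.6) and H2009 18 and 16 (81.0 and 81.3). Of its 70 regions, 18 were specific to BICR31 and 8 were exclusive to HCC95 and BICR31, among them chromosome 20, 49045937 to 49048106. A further 5 were specific to Ishikawa, among them 49359788 to 49362157. Genome-wide, the same classes held 15493, 2516 and 3607 of 70648 regions. With 250 kb flanks both H358 libraries (95.9 and 95.01) and Ishikawa replicate 1 (96.0) also reached 95, beside HCC95 at 95.2. USP12, a deubiquitinase gene, showed no line at a high percentile: the range over the 8 libraries was 60.4 to 73.6.

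Broad clusters of peaks differed between lines more than between replicates. The slope rule kept 1054 and 1341 clusters in H358, 969 and 1178 in H2009, 1453 in HCC95, 982 and 1562 in Ishikawa and 2532 in BICR31. Replicates shared 87.5% of the clusters of the shorter set in Ishikawa, 68.1% in H358 and 65.5% in H2009, and libraries of different lines 41.5% on average (30.7 to 55.4, 25 pairs). Replicates had the same file form, while most pairs of different lines did not. Within the narrowPeak lists, H358 with H2009 shared 46.6% to 52.0%, below the replicates of both lines. The highest value between lines was that of HCC95 with BICR31. With the other lines BICR31, the largest set, shared from 39.6% (Ishikawa replicate 2) to 51.5% (H358 replicate 1). A large set overlaps a shorter one more readily. In the MYC window of 350 to 550 kb, BICR31 had a kept cluster of 3 peaks at 129179990 to 129197898, rank 519 of 29736; the same place in H358 replicate 1, 129180159 to 129195346 with 5 peaks, ranked 1280 of 18468 and was not kept. In the PARD6B window BICR31 had 7 kept clusters and HCC95 3. Counts moved by over 1.5 times in 4 libraries with 5 kb stitching, for example from 2532 to 1358 in BICR31, and in 3 with 20 kb: HCC95 to 935, Ishikawa replicate 2 to 950 and BICR31 to 1653.

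The 4 further H2009 libraries set H3K27ac in cells labelled e3KRAB against cells labelled Empty and Control. Their lists were too short to address the window between 350 and 550 kb from MYC. Empty had 1960 peaks, Control 3250, e3KRAB1 2315 and the library labelled e3KRAB2 1375, and each list recovered only 4.57% to 10.7% of the peaks of an H2009 replicate. Between 350 and 550 kb from MYC, Empty had peaks at 129188532 to 129188824 and 129279380 to 129279721, e3KRAB1 had 1 at 129181029 to 129181340, and Control and the library labelled e3KRAB2 had 0. No region of this window was found in both Empty and Control, so a loss there was not detectable at this list length. Within 500 kb of MYC, e3KRAB1 had 6 peaks (1842 called bases, percentile 97.2), Empty 2, Control 1 and the library labelled e3KRAB2 0.

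Genome-wide, 281 of the 865 regions found in both Empty and Control had no peak in either e3KRAB list (32.5%, 95% Wilson interval 29.4 to 35.7). In the mirror set, 99 of 557 regions found in both e3KRAB lists had no peak in Empty or Control (17.8%, 14.8 to 21.2; two-sided Fisher's exact p = 6.82e-10 over regions). With lists of equal length the shares were 26.8% and 22.3% (Fisher's exact p = 0.136), so the difference was not kept once length was matched. Peak names in each short list carry the tag krab, then NoSg in Empty, D98 in Control, N1 in e3KRAB1 and Ctrl2 in the list labelled e3KRAB2. The tag Ctrl2 goes against its label, and the tag of the Control list names no control. This bears on each direction drawn from either list. Without the library labelled e3KRAB2, and with the Control list taken as labelled, 43.9% of 865 regions of Empty and Control lacked a peak in e3KRAB1. Of 689 regions of Empty and e3KRAB1, 29.8% lacked one in Control (Fisher's exact p = 8.94e-09). At equal length the shares were 41.7% and 39.6% (Fisher's exact p = 0.462). Of the peaks of each short list, 83.9% to 87.6% overlapped a peak of a given untreated H2009 replicate.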

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

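The test in this part was chosen after the peaks had been noticed and before its own result was seen. HCC95 had 282 peaks on alternate and unplaced sequences, which no comparison above uses, against 0 in the other 11 libraries. Of these, 193 lay on 7 alternate versions of part of chromosome 6, 19 on other alternate sequences and 70 on unplaced sequences, together 1.19% of the list. A candidate explanation is that HCC95 reads were aligned to a reference with alternate sequences, so that reads of the major histocompatibility complex on chromosome 6 were placed there or lost. Of 55 regions in the complex with a peak in each of the other 7 untreated libraries, 33 lacked an HCC95 peak, or 60% (95% Wilson interval 46.8 to 71.9), against 624 of 9178 elsewhere, or 6.80% (two-sided Fisher's exact p = 1.81e-24 over regions). The same measure for each of the other 7 libraries gave 0 or 1 region of 22 to 23. Those regions had to have an HCC95 peak, so they leave out the regions that HCC95 lacked and are not a like set. A loss of this region or of its acetylation in HCC95 would leave the same gap on chromosome 6 but would not place peaks on the alternate sequences; it was not tested and stays open.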

How the results depend on the processing

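Peak centres, the bound on −log10 q, the higher-ranked 50% of HCC95 and BICR31 alone, the set without BICR31, those without the library labelled e3KRAB2, and leaving out single libraries for agreement and clusters were chosen after seeing the data. The gain of agreement within lines kept its direction and side of the threshold in each setting, from 0.176 to 0.306 with 1 library left out. Among the main results, 73 values stayed, 38 moved and 2 lost their call; no difference changed sign, and the cause was not tested. Orders of counts did change. HCC95 (6001) passed BICR31 at equal lengths. Ishikawa passed HCC95 at 50% coverage (5517 in HCC95), in 1 kb bins and with a single replicate per line. H358 with H2009 passed HCC95 with BICR31 when only the latter lists were shortened. With the higher-ranked 50% of each list, specific regions were 370 in H358, 467 in H2009, 1964 in HCC95, 959 in Ishikawa and 7067 in BICR31, and pairs 898 for HCC95 with BICR31 and 151 for H358 with H2009. With equal lengths BICR31 had 5197, its pair with HCC95 1407, and H358 with H2009 rank 3. In 1 kb bins, another unit, HCC95 had 9243, Ishikawa 13872, BICR31 31164, HCC95 with BICR31 5013, and H358 with H2009 rank 6. At 50% coverage Ishikawa had 6583, HCC95 with BICR31 rank 2, and H358 with H2009 185. By peak centres H358 had 1632, H2009 1490, HCC95 7076, and H358 with H2009 1328 at rank 2. With only HCC95 and BICR31 held to 50%, their pair had 415 at rank 2, and H358 with H2009 690 at rank 1. Without BICR31, H358 had 1418, H2009 1537 and HCC95 7067. With a single replicate per line, H358 had 3935 to 3936, H2009 3619 to 4033, Ishikawa 6147 to 6911, and H358 with H2009 912 to 929. A region then needs 1 library and not 2, and fewer lists of other lines can break its exclusivity. Lines with 1 library throughout rose too, HCC95 to 4635 and 4766 and BICR31 to 17232 and 17378. In the short H2009 lists the difference of 14.7 points was 4.48 at equal length (Fisher's exact p = 0.136), and without the library labelled e3KRAB2 2.11 at equal length (0.462, Fisher's exact test). Of percentiles of single windows, read only as reaching 95 or not, and cluster counts, read within 1.5 times, 17 changed and 151 did not; below 95 percentiles could move far, as from 78.2 to 24.8 in HCC95 between 350 and 550 kb from MYC with the higher-ranked 50% of peaks. No paired analysis was possible because libraries of different lines share only a number, and a pair within a line always has different numbers. The alternatives for gene lists, for promoters and for removal of peaks near transcription starts were not run, since no annotation of the build was used. Read depth is unknown, and the short H2009 lists limit what can be seen.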

Other observations

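The tests of this part were all chosen after seeing the data, and for windows in HCC95 and BICR31 the prediction too was written after the shift had been seen. Line-specific regions were not spread evenly along the genome. In HCC95, 46 windows of 2 Mb held more of them than its genome-wide share gives (adjusted p under 0.05 by Fisher's exact test with Benjamini-Hochberg adjustment over 7295 windows), led by chromosome 11, 34000001 to 36000000, with 36 regions against 7.82 expected. The HCC95 peak of highest −log10 q, at chromosome 11, 34937004 to 34938847, lay in the same window. BICR31 had 49 such windows, led by chromosome 20, 46000001 to 48000000 (47 against 18.2). Ishikawa had 29, among them chromosome 3, 78000001 to 80000000 (12 against 1.38), and chromosome 18, 30000001 to 32000000 (12 against 1.89), which holds its widest specific region. H2009 had 11, led by chromosome 5, 8000001 to 10000000 (10 against 0.432), and H358 10, led by chromosome 12, 24000001 to 26000000 (7 against 0.816).

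A hypothesis for these windows is a local gain of read depth, as from extra DNA copies, which could lift regions over the calling threshold in 1 line. Regions called in every library ranked higher in the line than in the other lines inside its windows, by 17.1 percentile points in HCC95, 17.2 in BICR31, 10.2 in Ishikawa, 16.5 in H358 and 20.5 in H2009, each above the middle 95% of 10000 random sets of windows (permutation p = 0.0001 in HCC95 and BICR31, the smallest they can give, and 0.0084, 0.0004 and 0.0002). The test reads only windows that hold such regions, 36 of 46 in HCC95, 46 of 49 in BICR31, 17 of 29 in Ishikawa, 10 of 10 in H358 and 9 of 11 in H2009, and so not those named above for Ishikawa or for H2009. With fold enrichment in place of −log10 q, the shift passed the same bound in H358 (8.50 points, upper bound 6.74) but not in HCC95 (3.10, bound 3.59), H2009 (3.48, bound 7.32) or BICR31 (−1.56, bound 3.57); Ishikawa, whose own score ranking stayed while the other lines were ranked anew, had 8.14 (bound 7.72). A chromatin domain that is more active in 1 line may give the same shift, and copy number was not measured here, so both stay open.

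The exclusive share was highest for the lung adenocarcinoma pair and the squamous pair, which could come from shared lineage or from the calling of the lists. The number of libraries per line differed between these pairs and was not among the explanations tested. Unequal list length is argued against: with equal lengths the lower of their shares was 2.07 times the highest of the other pairs. The lower deposited threshold of HCC95 and BICR31 is argued against as well: at a −log10 q of at least 1.3 in these lists the ratio for their pair was 2.76, past the 1.5 set beforehand, and in the higher-ranked 50% of every list 1.67, although the higher-ranked 50% of these lists alone, which also shortens them against the others, gave 1.06. For peak width, peak centres gave 1.996, likewise past 1.5. The centre of a wide peak can, however, miss a narrow peak that the whole peak overlaps, which may favour pairs of 1 file form. Coverage of 50% gave 0.685, but that measure itself favours wide lists. Neither measure is free of width, so peak width stays open. Calling shared within a type cannot be told apart from lineage, because 0 pairs of different types have the same file form when HCC95 and BICR31 are grouped as squamous; by organ, or by the sample label of BICR31, that pair would itself be of different types with 1 form.

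The peak of highest −log10 q or score overlapped chromosome 1, 121484065 to 121485569, in 11 of the 12 lists, HCC95 being the exception with that place second in its order. Peaks were not filtered by place within a chromosome, and whether this signal reflects acetylation was not tested. The highest-scored cluster of both Ishikawa libraries also overlapped this place. The slope rule scales by the highest score, so their counts of 982 and 1562 kept clusters depend on it.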
